A study of Mus musculus and Homo sapiens with 14 samples.

How the data were processed

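The series measured messenger RNA in acute myeloid leukemia cells by polyA-selected RNA sequencing in 14 libraries that fall into 7 groups of 2, and every library entered a comparison. Per the submitters' processing notes, HISAT2, featureCounts and DESeq2 were used with the builds hg19 and mm10, and their versions are not given in the sources used here. The authors deposited 4 tables of DESeq2-normalized values, 1 for each comparison, in which every value is a gene's read count divided by the size factor of its library, so the deposited values are a signal on a linear scale and not raw counts. Each table was normalized separately by the authors, so tests were made within a table, except for the direct test of the knockouts, which used recovered reads of both RN2c tables, and levels set side by side across tables are given as such. The MOLM-13 table had 19166 rows and each of the mouse tables had 20682, all named by gene symbol.

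Because a size factor is the same for all genes of a library, the smallest nonzero value of a library is the worth of 1 read. Dividing by it gave whole numbers for 100 percent of the values in every library, with a largest deviation of 6.1e-10 reads. The recovered totals ranged from 13961461 to 24275290 reads per library. The sgRosa26 libraries in the sgSik3 and sgMef2c tables held the same recovered reads for every gene (0 genes differed in either library), so both comparisons share their controls. Between the libraries of a group, chi-square over degrees of freedom of the recovered reads ranged from 1.74 to 15.1, so no pair agreed within sampling noise and each library was counted once. Nothing in the labels says whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The sgSik3 libraries carried different guides, e1 and e3, as did the sgMef2c libraries, 1 and 2, so the spread within these groups includes the difference between guides.

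The design, the gene lists, the rule for named genes and the alternatives for the 4 comparisons listed at the end of this section were fixed before the data were examined. Chosen after seeing the data were, for the gene lists, TMM scaling, quantile normalization and leaving out a library, for the shared knockout calls, every alternative other than the threshold and the joint edgeR fit, and for the direct test, all but DESeq2. So were, for the sgMef2c sets, the pseudocount, the filter, the block and leaving out a library, for the correlation between the lines, the pseudocount and leaving out a library, and the tests that set RN2 calls against MOLM-13 and the knockouts. Genes with a mean value of at least 10 over the 4 libraries of a table were tested with limma 3.58.1 (empirical Bayes with a mean-variance trend, two-sided) on log2(value + 1) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are on this scale, which understates the change of low genes, and are given with their standard errors (SE). Since whole reads could be recovered, edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 (Wald test) were run on those reads as alternatives to the planned limma test. The direct test of sgMef2c against sgSik3 used edgeR on the recovered reads of the 6 RN2c libraries, with TMM factors.

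Named genes were, for each comparison, SIK1 to SIK3 and MEF2A to MEF2D, then the 10 largest rises and the 10 largest falls among genes past the test with a mean value of at least 50 and groups that did not overlap, passing over predicted or unnamed models. Where fewer than 5 passed in a direction, the genes of lowest p filled the number to 5 and are given as not past the test. Of each list described, up to 4 members with the lowest p were named, and of genes called in the same direction in both of 2 comparisons, the 10 in each direction with the largest of the smaller change. Genes named outside this rule are said to be chosen after their values were seen.

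There were 26 gene lists, covering SIK and MEF2 family members, targets of CREB and MEF2, the MLL fusion program, myeloid differentiation, MYC and ribosome biogenesis, stress and signaling responses, markers of other cell types, and signs of RNA quality. Of their symbols, 518 were matched in the mouse tables and 519 in the human table, older symbols included. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. With an estimated correlation, camera takes its degrees of freedom from the 4 libraries of a table, so even a clear shift can fail to pass. In RN2, the estimated correlation of the ERK feedback list was -0.021, below the preset, yet camera p went from 0.0092 to 0.10. Among lists called in sgSik3, the estimate was 0.023 for MYC and ribosome biogenesis, but 0.42 for granulocyte and 0.87 for sterol synthesis genes. Where the estimate lies far above the preset, camera p at the preset may be too small. No member of the mitochondrially encoded list was among the rows of the tables, and replication-dependent histones had 4 measured members in the mouse tables. In the knockouts, sets of up to 200 genes with the largest changes past the test were formed in each direction and tested in the YKL-05-099 comparisons with camera. Symbols were matched between species without regard to case.

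The fit was checked on simulated tables drawn from the library sizes and means of each comparison with 100 genes changed at each of 2 sizes. At a log2 change of 1, limma recovered 82.7 percent of the changed genes at MOLM-13 settings, 95 percent at RN2 settings, 92.8 percent at sgSik3 settings and 92 percent at sgMef2c settings. False calls made up 7.07, 3.55, 7.39 and 7.8 percent of the calls in that order, over 11288, 10689, 10888 and 10922 genes. The simulated libraries were drawn independently, without any deviation shared by replicate number. The planted changes also made the adjusted threshold easier to reach than in a table with few changed genes. These percentages therefore check the code and do not measure the power in the deposited tables, least of all in MOLM-13. The alternatives were pseudocounts of 0.1 and 10, no filter on low values, a mean value of at least 100, TMM scaling, quantile normalization, no mean-variance trend, the count tests, leaving out each library in turn (which leaves 1 library in its group, assumed to vary like the other group), the replicate number as a block, and for lists an estimated correlation and fry. Positions of mouse genes came from GENCODE release M21 on GRCm38, the assembly of mm10, in which 80 of 80 named mouse genes were found. A human annotation was not used here, so human genes are given by symbol. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.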

Results

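Messenger RNA was measured in 14 libraries of human and mouse acute myeloid leukemia cells, in 7 groups of 2. MOLM-13 is a human leukemia line that carries an MLL-AF9 fusion. RN2 is a mouse leukemia driven by MLL-AF9 and mutant Nras, and RN2c is the same leukemia with Cas9. MOLM-13 and RN2 cells were given YKL-05-099, an inhibitor of the salt-inducible kinases (SIKs), or 0.1% DMSO for 2 hours, at 250 nM in MOLM-13 and 350 nM in RN2. The titles of all these libraries carry the word empty, which is not interpreted here. RN2c cells received a guide RNA against Sik3, against Mef2c or against the Rosa26 locus, which serves as a control for cutting, and were collected on day 2 after infection. Recovered read totals ranged from 16859820 to 22609627 per library in MOLM-13, from 13961461 to 14943682 in RN2 and from 19065348 to 24275290 in RN2c. Values are DESeq2-normalized read counts as deposited, given as mean ± SD with n = 2 libraries per group.

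The sgSik3 comparison asked what cells lose or gain when the SIK3 kinase gene is cut. Sik3 itself (chromosome 9, 46012820 to 46224194 on GRCm38, a protein-coding gene on the plus strand) fell from 1908 ± 43.1 with sgRosa26 to 1194 ± 35.3 with sgSik3 (log2 fold change -0.68, SE 0.05, limma adjusted p = 5.7e-06), so transcript remained at 0.626 of the control level. The largest rises included genes of neutrophils. Mmp9, a matrix protease of neutrophils, rose 8.83-fold from 79.4 ± 24.5 to 692.6 ± 34.6, and Cd177, a neutrophil surface protein, rose 7.65-fold from 404.3 ± 42.9 to 3095 ± 269.3. The largest falls were Cd28, a costimulatory receptor (chromosome 1, 60716800 to 60773359), which fell 9.09-fold from 4440 ± 214.8 to 492.1 ± 94.6, and Hpgd, a prostaglandin-degrading enzyme, which fell 7.78-fold from 8801 ± 3328 to 1089 ± 58.7.

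Of 10934 genes tested with sgSik3, 5226 passed, 2611 higher and 2615 lower, with a median absolute log2 fold change of 0.32. More than 2-fold changes were found for 250 genes that rose and 165 that fell. The neutrophil granule genes Olfm4 (log2 fold change 2.56, SE 0.04), Ngp (2.42, SE 0.13) and Lcn2 (2.38, SE 0.09) rose, as did Lyz1, a lysozyme (2.55, SE 0.22), Timp2, an inhibitor of matrix proteases (2.36, SE 0.13), Gabbr1 (2.69, SE 0.23), Dennd2a (2.59, SE 0.39) and Zfp831 (2.49, SE 0.22). Lyz1 shares much of its sequence with Lyz2, so its reads are uncertain. Gfi1b, a transcriptional repressor of the erythroid and megakaryocytic lineages (chromosome 2, 28609450 to 28621982), had a log2 fold change of -2.80 (SE 0.16). Falls of similar size were measured for the growth hormone receptor Ghr (-2.63, SE 0.24), the chemokines Ccl4 (-2.49, SE 0.12) and Ccl3 (-2.23, SE 0.06), Hivep2 (-2.47, SE 0.14), Angptl2 (-2.30, SE 0.13), the integrin Itgb3 (-2.22, SE 0.11) and the potassium channel Kcnn4 (-2.18, SE 0.26). All of these had limma adjusted p of 0.000645 or less. Among the other SIK and MEF2 genes, Sik2 rose (0.48, SE 0.05, limma adjusted p = 0.00012), Mef2d fell (-0.40, SE 0.06, adjusted p = 0.0006) and Mef2c was slightly lower (-0.11, SE 0.03, adjusted p = 0.017). Sik1 (-0.10, SE 0.12) and Mef2a (0.07, SE 0.04) did not pass.

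Of 21 lists tested with sgSik3, camera called 9, 1 higher and 8 lower. With an estimated correlation, a test of little power at 4 libraries, none held (smallest adjusted p = 0.33). With fry, 4 of the 9 held. In the granulocyte list, 20 of 21 measured members rose and 0 fell, and the counts adjusted over the list alone were also 20 and 0 (camera adjusted p = 6.0e-12, adjusted p = 0.80 with an estimated correlation). Its leading members were S100a8 (2.35), S100a9 (2.30), Cd177 and Lcn2. In the list of MYC and ribosome biogenesis genes, all 30 members fell, and 30 did when adjusted over the list alone (camera adjusted p = 3.4e-18, adjusted p = 0.33 with an estimated correlation). Examples are the mitochondrial chaperonin Hspd1 (-0.83), the nucleolar proteins Npm1 (-0.70) and Mybbp1a (-0.63), and Myc (-0.73). The integrated stress response list had 13 of 24 members lower and 3 higher (adjusted over the list alone, 14 and 3), led by the serine and one-carbon enzymes Phgdh (-0.87), Mthfd2 (-0.58), Shmt2 (-0.55) and Psat1 (-0.46). Its camera adjusted p was 0.0012, and adjusted p = 0.80 with an estimated correlation. Nuclear oxidative phosphorylation genes fell in 17 of 25 cases and rose in 1 (adjusted over the list alone, 18 and 1), with Atp5a1 at -0.37 and Atp5b at -0.34 (camera adjusted p = 0.00021, adjusted p = 0.80 with an estimated correlation). Sterol synthesis genes fell in 12 of 21 cases (adjusted over the list alone, 12), with Fasn at -0.49 and Sqle at -0.50 (camera adjusted p = 0.00081, adjusted p = 0.91 with an estimated correlation). Of 23 p53 targets, 16 fell and 5 rose, also when adjusted over the list alone, with Cdkn1a at -0.47, Pmaip1 at -0.45 and Phlda3 at -0.999 (camera adjusted p = 0.0045, adjusted p = 0.80 with an estimated correlation). Heat shock genes fell in 7 of 11 cases, also when adjusted over the list alone (camera adjusted p = 0.0013, adjusted p = 0.80 with an estimated correlation), with Hsph1 at -0.58 and Hspe1 at -0.63. Hspd1 belongs to both this list and the MYC list. Genes of the unfolded protein response in the endoplasmic reticulum fell in 10 of 17 cases and rose in 2, also when adjusted over the list alone, with Hspa5 at -0.32 and Hyou1 at -0.33 (camera adjusted p = 0.034, adjusted p = 0.80 with an estimated correlation). Ribosomal protein genes fell in 12 of 29 cases, also when adjusted over the list alone, with Rps2 at -0.33 and Rpl3 at -0.18 (camera adjusted p = 0.017, adjusted p = 0.91 with an estimated correlation). Many ribosomal protein genes have near-identical pseudogenes, so their reads are uncertain. Without guide e3, the unfolded protein and ribosomal protein calls were lost (camera adjusted p = 0.051 and 0.19). The call of Mef2c was lost without either sgSik3 library (limma adjusted p = 0.10 without e1 and 0.089 without e3).

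The other 12 lists did not pass (smallest camera adjusted p = 0.22), although several held members that changed in both directions. Of 18 monocyte and macrophage genes, 8 fell (9 adjusted over the list alone), among them the chemokine receptors Cx3cr1 (-2.17) and Ccr2 (-1.62), and 4 rose, among them Lyz2 (1.13) and the Fc receptor Fcgr3 (0.77). Of 20 NF-kB and inflammation genes, 8 rose, including Il1b (2.28) and Nfkbia (0.56), and 4 fell, including Ccl3 and Ccl4. Of 25 genes of the MLL fusion and stem cell program, 11 rose, including Gfi1 (0.87) and Meis1 (0.57), and 7 fell, including Bcl2 (-0.96), and that list passed without sgRosa26 replicate 2 (camera adjusted p = 0.030). Markers of other cell types were few. In sgSik3, Cpa3, a mast cell protease (log2 fold change -1.53), and Vwf, a megakaryocyte and endothelial gene (-0.58), fell, and Nkg7 of cytotoxic lymphocytes (1.43), the megakaryocyte integrin Itga2b (0.50) and Pdgfrb of fibroblasts (0.30) rose. The call of Vwf was lost without sgRosa26 replicate 2 (limma adjusted p = 0.063) and without guide e1 (0.13), that of Itga2b without sgRosa26 replicate 1 (0.12), guide e1 (0.11) or guide e3 (0.13), and that of Pdgfrb without guide e3 (0.054).

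The sgMef2c comparison asked the same of the transcription factor MEF2C. Mef2c (chromosome 13, 83504034 to 83667080, a protein-coding gene on the plus strand) fell from 8382 ± 18.6 to 3957 ± 91.5 (log2 fold change -1.08, SE 0.04, limma adjusted p = 8.0e-05), leaving 0.472 of the control level. Neutrophil granule genes had the largest rises. Olfm4 rose 8.96-fold from 2239 ± 104.1 to 21408 ± 10606, Ngp rose 8.95-fold from 1353 ± 350.9 to 13241 ± 8177, and Lcn2 rose 7.95-fold from 411.8 ± 35.7 to 3449 ± 1525. Gfi1b had the largest fall, 7.37-fold from 223.3 ± 10.97 to 29.8 ± 7.18. The mast cell protease Cpa3 fell 4.67-fold, from 1134 ± 690.8 to 228.5 ± 94.7.

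Of 10956 genes tested with sgMef2c, 3442 passed, 1783 higher and 1659 lower, with 208 rising and 176 falling more than 2-fold. Rises included the antimicrobial peptide gene Camp (log2 fold change 2.68, SE 0.39), S100a9 (2.59, SE 0.28), Itgb2l (2.52, SE 0.37), the short-chain fatty acid receptor Ffar2 (2.51, SE 0.15), BC117090 (2.61, SE 0.25), Sept1 (2.59, SE 0.24) and Zfp831 (2.54, SE 0.26). Falls included Cd28 (-2.17, SE 0.14), Ccl4 (-2.17, SE 0.17), Cx3cr1 (-2.04, SE 0.11), Nlrc3 (-2.20, SE 0.35), the ephrin receptor Epha7 (-2.19, SE 0.27), the cadherin Cdh17 (-2.14, SE 0.19), Prrg4 (-2.11, SE 0.26) and the endocytic adaptor Dab2 (-2.02, SE 0.18). All had limma adjusted p of 0.00435 or less, except Cpa3 at 0.0089. Mef2d fell (-0.38, SE 0.07, limma adjusted p = 0.0087), Sik1 (0.52, SE 0.13, adjusted p = 0.021) and Sik2 (0.29, SE 0.06, adjusted p = 0.013) rose, and Sik3 (0.09, SE 0.04) and Mef2a (-0.19, SE 0.08) did not pass, although Mef2a passed without guide 1 (limma adjusted p = 0.0097). The call count was 1628 without the mean-variance trend, 2255 with DESeq2, and 2206 without sgRosa26 replicate 1, 2119 without sgRosa26 replicate 2 and 1815 without guide 2. The change was larger with guide 2 than with guide 1 in 84.1% of the called genes, and the slope of the guide 2 changes on those of guide 1 was 1.25, against 0.95 between the sgSik3 guides.

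Of 22 lists tested with sgMef2c, camera called 10, 2 higher and 8 lower. With an estimated correlation, again of little power at 4 libraries, none held (smallest adjusted p = 0.64). With fry, 0 of the 10 held. Granulocyte genes rose in 17 of 21 cases and 1 fell, also when adjusted over the list alone (camera adjusted p = 4.2e-09, adjusted p = 0.64 with an estimated correlation). Myeloperoxidase, Mpo (1.53), neutrophil elastase, Elane (0.77), the transcription factor Cebpe (1.27) and the receptor Csf3r (0.81) led this list, and the chemokine receptor Cxcr2 was the member that fell (-0.52). The MYC and ribosome biogenesis list had 29 of 30 members lower, also when adjusted over the list alone, with Npm1 at -0.43, Nolc1 at -0.39, Hspd1 at -0.49 and Utp20 at -0.38 (camera adjusted p = 1.7e-13, adjusted p = 0.64 with an estimated correlation). Monocyte and macrophage genes fell in 10 of 18 cases and rose in 2 (adjusted over the list alone, 12 and 3), with Cx3cr1, Cd14 (-0.85), Cd68 (-0.62) and Ccr2 (-1.82) lower (camera adjusted p = 0.00066, adjusted p = 0.64 with an estimated correlation). Cell cycle genes rose in 10 of 32 cases and none fell (adjusted over the list alone, 11 and 0), with Mki67 at 0.29 and Kif11 at 0.22 (camera adjusted p = 0.0024, adjusted p = 0.64 with an estimated correlation). The integrated stress response list had 13 of 24 members lower (adjusted over the list alone, 16 lower and 2 higher), with the amino acid transporter Slc7a5 at -0.47 (camera adjusted p = 0.00066, adjusted p = 0.64 with an estimated correlation). Of 23 p53 targets 15 fell and 3 rose, also when adjusted over the list alone, with Cdkn1a at -0.49 and Sesn1 at -0.53 (camera adjusted p = 0.002, adjusted p = 0.64 with an estimated correlation). Heat shock genes fell in 6 of 11 cases (adjusted over the list alone, 8), with camera adjusted p = 0.0067 and adjusted p = 0.64 with an estimated correlation. Genes of ERK feedback and the immediate early response fell in 9 of 25 cases and rose in 2, also when adjusted over the list alone, with the cyclin Ccnd1 at -1.28, Fos at -0.74 and Myc at -0.36 (camera adjusted p = 0.023, adjusted p = 0.64 with an estimated correlation). Sterol synthesis genes fell in 5 of 21 cases, also when adjusted over the list alone (camera adjusted p = 0.029, adjusted p = 0.78 with an estimated correlation), and unfolded protein response genes fell in 5 of 17 cases and rose in 2, also when adjusted over the list alone (camera adjusted p = 0.031, adjusted p = 0.65 with an estimated correlation). The sterol call was lost without sgRosa26 replicate 1 (camera adjusted p = 0.54) and without guide 2 (0.10), the unfolded protein call without those same libraries (0.0709 and 0.0851), and the ERK call without guide 1 (0.10). The other 12 lists did not pass, of which nuclear oxidative phosphorylation came closest (camera adjusted p = 0.051, and 0.036 without guide 1). Ribosomal proteins were among these, with 0 of 29 members past the test. The calls of Sik1 (limma adjusted p = 0.083 without sgRosa26 replicate 1, 0.053 without sgRosa26 replicate 2 and 0.13 without guide 2), Sik2 (0.062 without sgRosa26 replicate 2 and 0.054 without guide 1) and Cxcr2 (0.069, 0.17 and 0.21 without sgRosa26 replicate 1, sgRosa26 replicate 2 and guide 2) were lost when a library was left out.

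**Figure D1:**
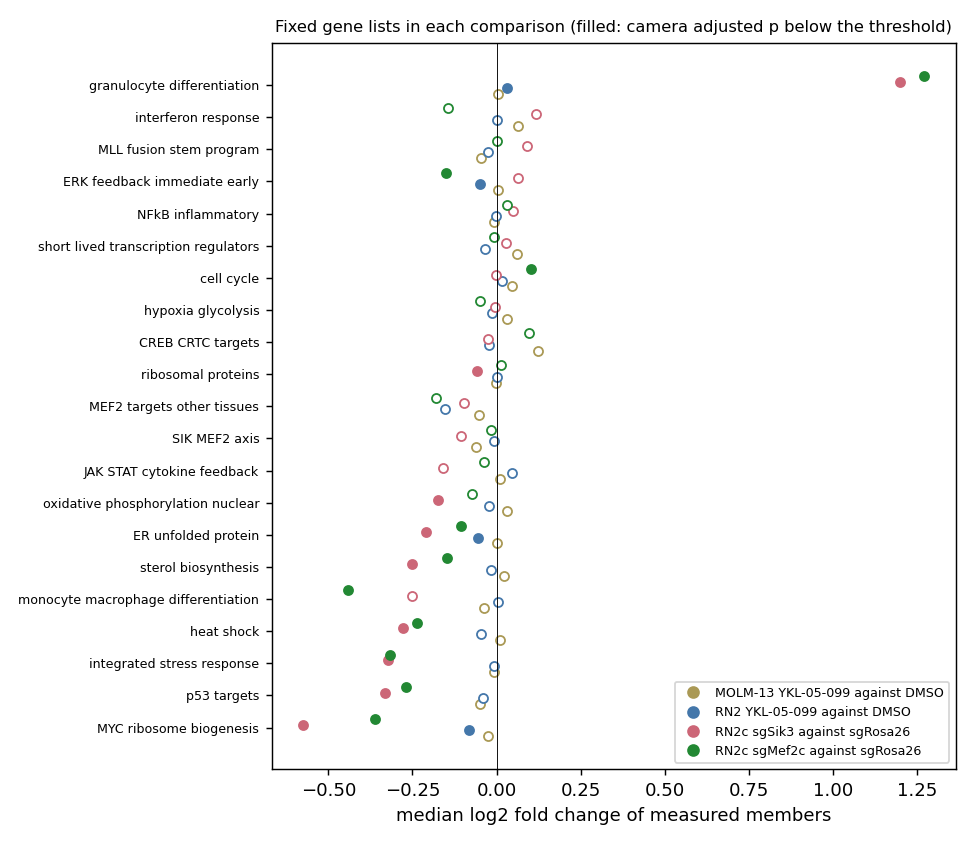
Median log2 fold change of the measured members of each fixed gene list (horizontal axis) in the 4 comparisons, with filled points for lists called by camera. The granulocyte list lies highest in both knockouts and the MYC and ribosome biogenesis list lowest in sgSik3 (median -0.57), while medians in the YKL-05-099 comparisons lie close to 0.

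The knockout comparisons were then set side by side. Among 10893 genes tested in both, 1573 rose in both and 1394 fell in both, against 422.8 and 397.6 for independent lists, and 21 changed in opposite directions. The shared rises were led by Olfm4, Zfp831, Ngp and Lcn2, followed by Ces1d (2.35 with sgSik3 and 2.48 with sgMef2c), S100a8, S100a9, Dennd2a, the complement gene C3 (2.16 and 2.18) and Lrg1 (2.15 and 2.21). The shared falls were led by Gfi1b, Cd28, Ccl4, Prrg4 (-2.05 with sgSik3), Cx3cr1, Dab2 (-2.13 with sgSik3) and Ghr (-1.92 with sgMef2c), followed by Abcb1b (-1.92 and -1.83), Kcnn4 (-1.79 with sgMef2c) and Lhfp (-1.76 and -1.93). The log2 fold changes correlated across genes with Pearson's r of 0.86 and Spearman's rho of 0.83, and genes are not independent replicates. The same sgRosa26 libraries enter both comparisons. In a simulation, unchanged groups and the controls they shared were all drawn independently around the sgRosa26 means. It gave r of 0.51 on average and 0.56 at most over 100 draws. The measured covariance was 0.153, against 0.0091 in the simulation. The measured deviations of the sgRosa26 libraries did not enter the draws. The simulation therefore cannot show what a handling difference common to these libraries would give. The simulated groups shared at most 3 higher and 3 lower calls, and 2 sgRosa26 libraries are too few to give each knockout its own 2 controls. The shared count of 2967 became 1372 without the mean-variance trend, 1929 with DESeq2, 1965 without sgRosa26 replicate 2 and 1676 without sgMef2c guide 2.

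**Figure D2:**
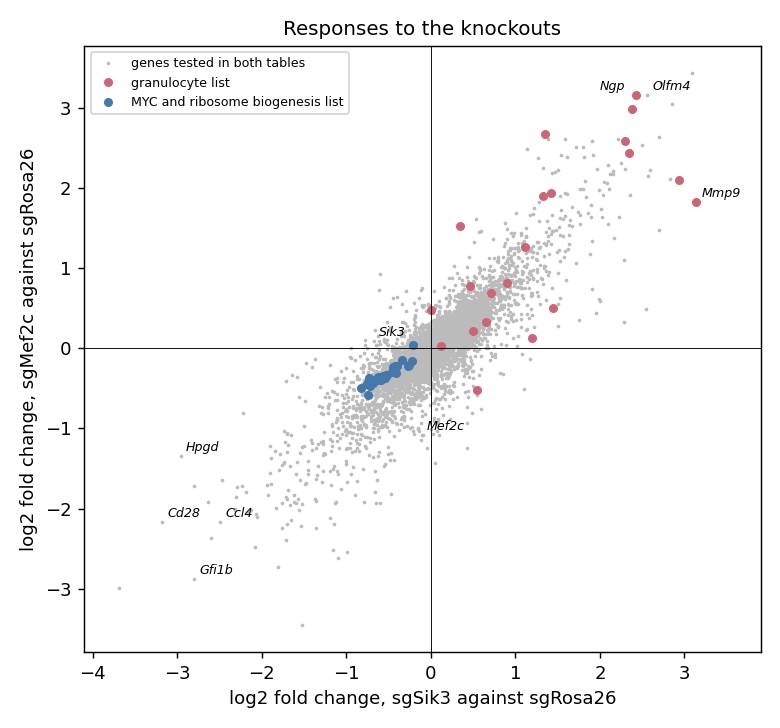
Log2 fold change of each gene tested in both RN2c tables, with sgSik3 on the horizontal and sgMef2c on the vertical axis, granulocyte genes in red and MYC and ribosome biogenesis genes in blue. Genes spread along the diagonal (Pearson's r of 0.86 across 10893 genes), with granulocyte genes mostly at the upper right and MYC genes at the lower left.

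Tested directly against each other, the knockouts differed in 1034 of 10954 genes by edgeR, with 405 higher and 629 lower in sgMef2c. Hpgd (log2 difference 1.61, edgeR adjusted p = 0.0032) and Itgb3 (1.40, adjusted p = 0.00022) fell further with sgSik3. The transporter gene Slco4a1 (1.29, adjusted p = 4.4e-05) had log2 fold changes of -1.47 with sgSik3 and -0.18 with sgMef2c. The latter did not pass with all libraries (limma adjusted p = 0.054), but did without guide 1, at -0.25. Mpo (1.17, adjusted p = 3.7e-05) rose further with sgMef2c. The matrix glycoprotein Thbs1 (-1.23, adjusted p = 5.6e-05), the interleukin-1 receptor antagonist Il1rn (-1.35, adjusted p = 0.0025), the transglutaminase Tgm2 (-1.41, adjusted p = 0.00022) and Mmp9 (-1.23, adjusted p = 0.026) were lower in sgMef2c than in sgSik3. Of the 30 MYC and ribosome biogenesis genes, 19 were higher in sgMef2c and 0 lower, with a median log2 difference of 0.21. Of 18 monocyte and macrophage genes 7 were lower in sgMef2c and 0 higher, and of 32 cell cycle genes 6 were higher and 0 lower. No set test was made of these differences, and most of these calls were lost without sgSik3 e1 or e3. Median log2 differences without e1 and e3 were 0.22 and 0.21 for MYC and ribosome biogenesis genes. They were 0.085 and 0.070 for cell cycle genes, and -0.24 and -0.22 for monocyte and macrophage genes. The call of Mmp9 with sgMef2c (1.82) was lost without sgRosa26 replicate 1, where its log2 fold change was 1.51. These genes were chosen from the direct test after its values were seen. The count of 1034 became 50 without sgSik3 e1, 50 without sgSik3 e3 and 633 without sgMef2c guide 1, and it was 606 with DESeq2.

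In RN2 cells, the comparison asked which transcripts respond within 2 hours to YKL-05-099. The chemokine genes Ccl3 (chromosome 11, 83647844 to 83649355) and Ccl4 (chromosome 11, 83662584 to 83664683) had the largest falls, 3.30-fold from 1637 ± 341.7 to 490.2 ± 40.4 and 2.99-fold from 327.1 ± 66.3 to 107.7 ± 9.36. Cd28 fell 2.32-fold from 3308 ± 109.2 to 1423 ± 31.5. The phosphatase gene Phlpp2 fell 2.28-fold from 1347 ± 56.2 to 591.9 ± 37.1. The largest rise was Map2k6, a kinase of the p38 pathway, 1.75-fold from 129.4 ± 7.90 to 226.6 ± 1.22. Sik1, Sik2, Sik3, Mef2a, Mef2c and Mef2d did not pass, with log2 fold changes of 0.29, -0.07, 0.03, 0.01, -0.07 and -0.02.

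Of 10732 genes tested in RN2, 34 passed, 4 higher and 30 lower (499 with the replicate number as a block, though no pairing is labeled). The largest falls also included Fam84b (log2 fold change -1.14, SE 0.07), the potassium channel Kcnj2 (-1.07, SE 0.09), the immediate early gene Egr1 (-0.86, SE 0.11), Hpgd (-0.85, SE 0.06), Gfi1b (-0.83, SE 0.13) and Tnfaip3, a negative regulator of NF-kB (-0.73, SE 0.12). The rises were Map2k6 (0.80, SE 0.12), the myeloid receptor Trem1 (0.62, SE 0.10), Lbh (0.56, SE 0.09) and the cytokine Il16 (0.42, SE 0.05). Gbp7 (0.52, SE 0.09) did not pass (limma adjusted p = 0.055), but did without DMSO replicate 1 (0.013) or 2 (0.0019). Members of the fixed lists that fell included Myc (-0.55, limma adjusted p = 0.026), the myeloid transcription factors Irf8 (-0.36, adjusted p = 0.024) and Zeb2 (-0.35, adjusted p = 0.0041), and the RNA-binding protein Zfp36 (-0.44, adjusted p = 0.047). The count was 30 with edgeR and 34 with DESeq2, but 3 with no filter on low values, 16 after quantile normalization and 0 without the mean-variance trend, and it was 130 without DMSO replicate 1 and 321 without DMSO replicate 2. Leaving out 1 of the YKL-05-099 libraries ended the calls of Map2k6 (limma adjusted p = 0.076 and 0.079 without replicates 1 and 2), Trem1 (0.15 and 0.28), Lbh (0.076 and 0.34), Tnfaip3 (0.12 and 0.052) and Zfp36 (0.0775 and 0.25), and that of Gfi1b without replicate 1 (0.061).

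Of 21 lists tested in RN2, camera called 4 (9 with the replicate number as a block, though no pairing is labeled). None held with an estimated correlation, which has little power at 4 libraries (adjusted p = 0.41 for each of the 4). With fry, 0 of the 4 held. The MYC and ribosome biogenesis list was lower, with 1 of 30 members past the test and 7 adjusted over the list alone, and a median of -0.08 (camera adjusted p = 1.1e-11). Myc was the member past the test, and Ppan (-0.21), Tfrc (-0.14) and Gnl3 (-0.19) followed, of which Ppan and Tfrc passed without DMSO replicate 2 (limma adjusted p = 0.031 and 0.0053). The unfolded protein response list was lower (camera adjusted p = 0.00035), with Edem1 past the test (-0.23) and 1 adjusted over the list alone. The ERK feedback and immediate early list was lower (camera adjusted p = 0.048), with 2 of 24 members past the test, Egr1 and Myc, and 7 lower and 1 higher adjusted over the list alone. The granulocyte list was higher with none of 21 members past the test or adjusted over the list alone (camera adjusted p = 0.048), a median of 0.03 and Cd177 at 0.34. The granulocyte call was lost without DMSO replicate 2 (camera adjusted p = 0.13) and without YKL-05-099 replicate 1 (0.39), the ERK call without DMSO replicate 2 (0.055), and the call of Edem1 without YKL-05-099 replicate 2 (limma adjusted p = 0.10). Without the block, the other 17 lists did not pass (smallest camera adjusted p = 0.062). In the NF-kB and inflammation list, at that value, Ccl3, Ccl4 and Tnfaip3 passed among 16 members, and the list was called with any 1 library left out (camera adjusted p of 0.017 or less), but adjusted p was 0.41 with an estimated correlation. The number of called lists rose from 4 to 15 without DMSO replicate 1, 6 without YKL-05-099 replicate 1 and 9 without YKL-05-099 replicate 2.

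Genes that fell with YKL-05-099 in RN2 were compared with those that fell in the knockouts, which used other libraries. Of the 30 genes, 28 also fell with sgSik3, against 7.36 for independent lists, and 26 with sgMef2c, against 4.65 (Fisher's exact test, Benjamini-Hochberg adjusted p = 1.1e-14 and 8.6e-17 over the overlaps computed). Genes are not independent replicates, so these p-values do not measure the spread between libraries. Both knockouts share their sgRosa26 libraries, so the overlaps are not separate evidence. Ccl3, Ccl4, Cd28, Phlpp2, Fam84b, Kcnj2, Hpgd, Gfi1b, Tnfaip3, Cpeb2 and Tlr13 fell in all 3 comparisons, and Slco4a1 fell with the compound (-0.69) and with sgSik3. Cd28 had log2 fold changes of -1.22 with the compound, -3.18 with sgSik3 and -2.17 with sgMef2c, and Phlpp2 of -1.19, -1.79 and -1.31. Egr1, in contrast, rose with sgSik3 (0.47), and Rev1, a DNA polymerase gene that fell with the compound (-0.35), was higher with sgSik3 (0.23) and sgMef2c (0.17). Egr1 and Rev1 were chosen after their values were seen. The call of Rev1 was lost in RN2 without YKL-05-099 replicate 1 (limma adjusted p = 0.0775) and in sgMef2c without sgRosa26 replicate 1 (0.059) or 2 (0.087), that of Cpeb2 in RN2 without YKL-05-099 replicate 2 (0.072), and that of Tnfaip3 in sgMef2c without sgRosa26 replicate 2 (0.061) or guide 2 (0.055). Of the 4 genes that rose with YKL-05-099, 3 (Trem1, Lbh and Il16) also rose with sgSik3 (0.96 for independent lists, adjusted p = 0.22) and 2 (Trem1 and Il16) with sgMef2c (0.65, adjusted p = 0.51).

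As a set, the 200 genes with the largest falls in sgMef2c were lower in RN2 cells given YKL-05-099, with 9 of 184 measured members past the test and a median log2 fold change of -0.05 (camera p = 0.0015, p = 0.44 with an estimated correlation). The 200 genes with the largest rises were higher, with 0 of 145 past the test and a median of 0.12 (camera p = 5.8e-09, p = 0.088 with an estimated correlation). Sets from sgSik3 gave 13 of 184 lower members with a median of -0.04 (camera p = 0.0014, p = 0.39 with an estimated correlation) and 1 of 135 higher members with a median of 0.16 (camera p = 1.3e-11, p = 0.12 with an estimated correlation). For the granule genes that led the knockout rises, the compound gave log2 fold changes of 0.11 for Olfm4, 0.16 for Ngp and 0.28 for Lcn2, none of them past the test. The genes lowered by sgMef2c were no longer lower as a set at the preset correlation without DMSO replicate 2 (camera p = 0.56) or without YKL-05-099 replicate 1 (camera p = 0.28).

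**Figure D3:**
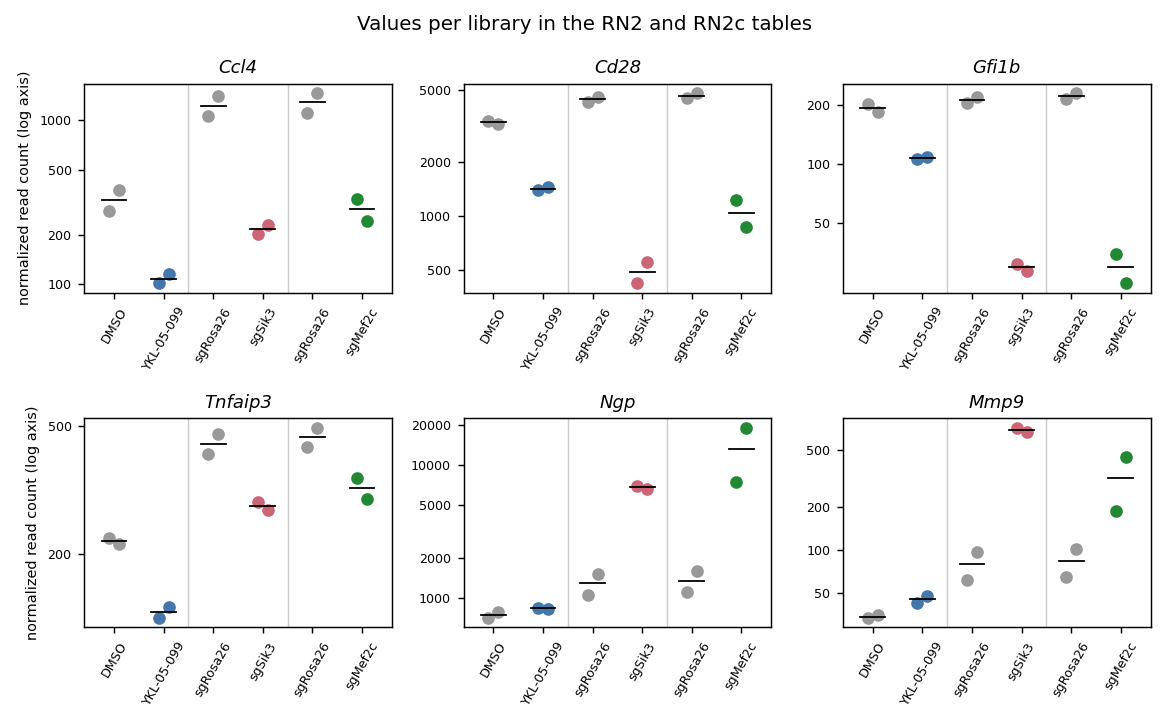
Normalized read count of 6 genes in each library (log axis), with horizontal lines at the group means, for RN2 cells given DMSO or YKL-05-099 and for the sgRosa26 libraries beside sgSik3 and beside sgMef2c in their separately normalized tables. Ccl4, Cd28, Gfi1b and Tnfaip3 lay below the controls in all 3 treated groups, while Ngp and Mmp9 lay far above them in the knockouts and near them with the compound.

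In MOLM-13 cells, the same question was asked of the human line, and no gene passed limma in the fit without a replicate block. The lowest p values belonged to SHISA2 (247.9 ± 70.4 with DMSO and 57.8 ± 4.73 with YKL-05-099, log2 fold change -2.05, SE 0.23), CDC42EP3 (-0.69, SE 0.10), TNFAIP3 (767.1 ± 121.2 and 361.1 ± 79.7, -1.09, SE 0.19), and MKL1 (-0.46, SE 0.09) among lower genes, and 1 further gene chosen by the rule is not analysed here. Among higher genes they belonged to ICOSLG, a costimulatory ligand (1191 ± 10.1 and 1853 ± 20.4, 0.64, SE 0.09), the interleukin-10 receptor IL10RA (1.08, SE 0.17), the growth factor HBEGF (0.86, SE 0.15), DDIT4, a stress-induced inhibitor of mTORC1 (1.03, SE 0.18), and TNFSF14 (0.68, SE 0.12). SIK1, SIK2 and SIK3 had log2 fold changes of 0.12, 0.03 and -0.08, and MEF2A, MEF2B, MEF2C and MEF2D of -0.01, -0.02, 0.06 and -0.02.

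Of 11361 genes tested in MOLM-13, 0 passed limma (smallest adjusted p = 0.52) and 0 passed edgeR, while 144, or 1.27%, had an unadjusted limma p under 0.05. Libraries with the same replicate number deviated together (correlation 0.53), and these fits count that as spread. With the replicate number as a block, limma called 290 genes, 140 higher and 150 lower, although the labels state no pairing. The count of 0 is therefore no sign that the compound had no effect. DESeq2 called 7 genes, 4 lower (SHISA2, OCSTAMP, TNFAIP3 and CDC42EP3) and 3 higher (DDIT4, IL10RA and ICOSLG). With 1 library left out, limma called 16 genes without DMSO replicate 1, 15 without DMSO replicate 2, 14 without YKL-05-099 replicate 1 and 20 without YKL-05-099 replicate 2. Each of these fits has 1 library in an arm and takes its spread from the other arm alone. Without the block, none of 23 lists was called (smallest camera adjusted p = 0.081), while camera called 2 with it. No member passed over all genes without the block, although PDE4B, a target of CREB, had a log2 fold change of 1.64 and NR4A2 of 0.82. PDE4B was called without DMSO replicate 1 (limma adjusted p = 0.012) and without YKL-05-099 replicate 2 (0.020). With 1 library left out, camera called 10 lists without DMSO replicate 1, 11 without DMSO replicate 2, 7 without YKL-05-099 replicate 1 and 4 without YKL-05-099 replicate 2. Of 65 measured genes of the major histocompatibility region, 49 had a mean value under 10 in this table, and TNF was listed at 0 in all 4 libraries.

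Between the lines, log2 fold changes of YKL-05-099 correlated weakly across 8834 shared symbols, with Pearson's r of 0.11 and Spearman's rho of 0.10, at different doses and in separately normalized tables. Pearson's r was 0.055 without MOLM-13 DMSO replicate 1 and 0.034 without MOLM-13 YKL-05-099 replicate 2. Since no gene passed in MOLM-13 without the block, no calls were shared in that fit. Of the 20 genes that fell in RN2 and were measured in MOLM-13, 12 had a negative change there (camera p = 0.0028, p = 0.083 with an estimated correlation), and of 3 that rose, 3 had a positive one (camera p = 2.1e-06, p = 0.073 with an estimated correlation). The values were -1.72 for Ccl3 and -1.11 for CCL3, -0.73 for Tnfaip3 and -1.09 for TNFAIP3, -0.55 for Myc and -0.42 for MYC, -0.36 for Irf8 and -0.26 for IRF8, 0.80 for Map2k6 and MAP2K6, and 0.42 for Il16 and 0.57 for IL16. For these 6 the MOLM-13 groups did not overlap, which chance gives in 1 direction or the other for 1 gene in 3, and they were chosen after their values were seen. Among genes called in RN2, the MOLM-13 groups were also separate for DOT1L (-0.19), lower in both lines. They were separate in the opposite direction for FAM84B (0.42) and RAPH1 (0.31), which fell in RN2. The knockout-derived sets were not called in MOLM-13 (camera adjusted p of 0.13 to 0.45 over the 4 sets).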

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

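The values here were found by comparing the changes of the same gene in 2 cell lines after the results were seen. Fam84b fell with YKL-05-099 in RN2 cells, from 992.7 and 965 with DMSO to 451.9 and 434.8 with the compound (log2 fold change -1.14, limma adjusted p = 4.1e-05), while FAM84B in MOLM-13 was higher in both treated libraries, at 30.1 and 28.7 against 25.2 and 18.8 (0.42, not past the test). It is given here because every library of 1 line moved opposite to every library of the other under the same contrast. Groups of 2 libraries often separate by chance, as stated for the comparison of the lines, so this is weak evidence of a difference. Raph1, outside the named genes, did likewise. Its log2 fold change was -0.62 in RN2 (limma adjusted p = 0.027) and 0.31 in MOLM-13, not past the test. Neither difference was tested, the MOLM-13 values of FAM84B are low, and the doses were 350 nM in RN2 and 250 nM in MOLM-13.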

How the results depend on the processing

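Of 3347 gene results under other settings, 3134 kept their side of the threshold, 138 lost their call, 75 gained one and 0 turned direction. Of these, leaving out a library ended 40 calls and began 39, and leaving out the mean-variance trend ended 47. Cd28, Ccl3 and Hpgd were called in RN2 and in both knockouts with any 1 library left out. For lists, 809 of 932 results stayed, 53 lost their call, 63 gained one and 7 turned direction. All 7 came from leaving out a library in lists that were not called with all libraries. Leaving out a library leaves the replicate numbers unbalanced between DMSO and YKL-05-099. In replicate 1 against 2, p53 targets were higher in MOLM-13, and the other turned lists were lower in their table. Every one of the 7 turned the way that this imbalance would move it, and no further cause was tested. In MOLM-13, camera adjusted p ranged over the libraries left out from 0.00801 to 0.296 for the unfolded protein list (0.0300 in the opposite direction without DMSO replicate 1), from 2.1e-07 to 0.121 for the integrated stress response (0.00455 likewise), from 3.4e-05 to 0.0328 for p53 targets (opposite at 0.0164 without DMSO replicate 1 and 0.0328 without YKL-05-099 replicate 2), from 0.00643 to 0.464 for short-lived transcription regulators (0.0180 likewise) and from 5.8e-07 to 0.0976 for sterol synthesis (0.00455 likewise). In RN2 the integrated stress response list ranged from 4.4e-04 to 0.244, with 0.00245 in the opposite direction without DMSO replicate 2.

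The MOLM-13 count of 0 became 7 with DESeq2 and 14 to 20 with a library left out. The RN2 count of 34 became 3 with no filter on low values, where more genes were tested, 16 after quantile normalization, 0 without the mean-variance trend, and 28 to 321 with a library left out. The sgMef2c count of 3442 became 1628 without the trend, 2255 with DESeq2 and 1815 to 3138 with a library left out, and the sgSik3 count stayed within 1.5 times under every setting (3532 with DESeq2). The count of 23 called lists became 0 with an estimated correlation and 5 with fry. All 5 fry calls were in sgSik3, where 4 of the 9 lists called by camera held. The other was the monocyte and macrophage list (fry adjusted p = 0.041), which camera did not call. In RN2 and sgMef2c, fry called 0 lists. The 2967 shared knockout calls became 1427 at an adjusted p under 0.01, where the threshold itself is stricter, 1372 without the trend, 1929 with DESeq2 and 1676 to 2768 with a library left out. The direct count of 1034 became 606 with DESeq2 and 50 to 1152 with a library left out. For the sets from sgMef2c in RN2, camera p with an estimated correlation was 0.443 for genes that fell and 0.0877 for genes that rose, and at the preset correlation with a library left out it was 1.5e-11 to 0.564 for genes that fell. Pearson's r between RN2 and MOLM-13 was 0.0336 to 0.147 with a library left out. For these counts and values the cause was not tested, other than where a stricter threshold gives it. The number of genes tested does not by itself give the fall from 34 to 3 in RN2. There were at most 20682 rows, against 10732 genes tested in the main fit. Cd28, Phlpp2, Fam84b, Hpgd and Ccl3 had limma adjusted p of 9.8e-05 or less in the main fit.

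With the replicate number as a replicate block, limma called 290 genes in MOLM-13, 499 in RN2 and 3905 in sgMef2c, where the number is that of the guide, and camera called 2, 9 and 10 lists. The 2 in MOLM-13 were the MLL fusion program, lower (camera adjusted p = 5.8e-04), and the cell cycle, higher (0.0498). In RN2, the lists called with the block but not in the main fit were all lower. They were NF-kB and inflammation (camera adjusted p = 2.7e-10), short-lived transcription regulators (0.0016), the MLL fusion program (0.0025), heat shock (0.0082) and p53 targets (0.025). Deviations of libraries with the same number correlated at 0.53 in MOLM-13, 0.22 in RN2 and 0.05 in sgMef2c. Among genes with a mean of at least 1000 the correlations were 0.878, 0.517 and 0.127 in that order. The labels state no pairing and 2 pairs are few, so the blocked fit is given only beside the main counts of MOLM-13 and RN2. The list medians near 0 that changed sign after quantile normalization belonged to lists that were not called. Depth leaves genes with a mean value under 10 untested, and the simulation was not split by level, so what depth limits among tested genes was not measured.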

Other observations

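The tests of low expression of the major histocompatibility region, of the p53 targets by replicate number, of the response shared with YKL-05-099 and of the handling of sgRosa26 were chosen only after the results were seen, those of library size and of separate control libraries before, and that of second gene copies after the low values of the region but before the values it measures. A first test of low expression of that region used 4 genes picked because they were at 0, which fixed its outcome, and was replaced by genes chosen by function, with the values already seen. A first test of second copies measured only the low values of the region itself and was also replaced. The genes in this paragraph were also chosen after their values were seen. Of the 21 genes called in opposite directions in the knockouts, Dhx40 rose with sgSik3 and fell with sgMef2c (log2 fold change 0.81 and -0.31), as did the C-type lectin gene Clec4d (0.48 and -0.81), the macrophage growth factor gene Csf1 (0.22 and -0.72) and the neutrophil chemokine receptor gene Cxcr2 (0.55 and -0.52). The sgSik3 call of Csf1 was lost without sgRosa26 replicate 1 (limma adjusted p = 0.20), guide e1 (0.10) or guide e3 (0.23). Cxcr2 was not called in sgSik3 without guide e1 (limma adjusted p = 0.071) and not in sgMef2c without either sgRosa26 library or guide 2. Among markers of other lineages, Nkg7, a granule gene of cytotoxic lymphocytes, rose in both (1.43 with sgSik3 and 1.67 with sgMef2c) and Vwf fell with sgMef2c (-0.95, a call lost without sgRosa26 replicate 2, limma adjusted p = 0.053). Gata2, a stem cell and mast cell regulator, fell with sgMef2c (-0.35) and did not pass with sgSik3 (-0.01). In RN2, 13824 and 14578 genes had a read in replicate 1 of DMSO and YKL-05-099, against 13162 and 13142 in replicate 2.

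Of 65 measured genes of the major histocompatibility region, 49 had a mean under 10 in MOLM-13, and the highest means were those of RPS18 (218.6), TCF19 (112.7) and BRD2 (101.1). RPS18 stood at 738.0 in DMSO replicate 1 and at 22.0 to 82.1 in the other libraries, so its rank rests on 1 library. TNF, TAP1 and IER3 were listed at 0 in all 4 libraries, against means of 290.1, 1089 and 153.0 in RN2, and over the 65 genes the median log2 ratio of MOLM-13 to RN2 was -8.35, where 10000 random lists matched on the RN2 value gave -0.56 to 0.82. If reads with several equal alignments, as to alternate haplotype copies, were not counted, genes elsewhere with a second copy in hg19 would be low too, and 8 such genes of the pseudoautosomal regions and a chromosome 17 haplotype had a median log2 ratio of -4.71 (random lists -2.99 to 2.01), which fits, although NSF (-0.11) and PLCXD1 (-0.24) were not low. Low expression of the whole region would spare genes that dividing cells need, but the 12 listed genes of tRNA charging, ribosomes and their assembly, splicing, general transcription and prefoldin had a median value of 0.931 (0 to 1.71 by library), where random lists matched on the RN2 value gave 262.2 or more, which argues against it. Interleukin-3 and GM-CSF receptor genes, IL3RA and CSF2RA, which lie outside this region, were also low, at means of 2.54 and 2.93. They are pseudoautosomal, so uncounted reads could explain them too, and their low values do not show absent receptors. Their values had been looked at before, so they were left out of the test of second copies.

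In MOLM-13, libraries with the same replicate number deviated together from their group means (correlation 0.53), and 4332 of 11361 genes differed by replicate number. If library size caused this, abundant genes would deviate little together, but the correlation was 0.878 among 4581 genes with a mean of at least 1000, which argues against library size. HMOX1, a heme oxygenase induced by oxidative stress, stood at 907.8 and 925.8 in replicate 1 of DMSO and YKL-05-099 and at 255.8 and 236.9 in replicate 2, and MDM2, a p53 target, at 5576 and 5254 against 2310 and 2207. The p53 target list differed by replicate number (camera adjusted p = 0.00129, adjusted p = 0.71 with an estimated correlation), but so did 14 of 23 lists, so a culture or handling difference that moved p53 targets cannot be told apart from a broader one, a condition on the other lists that was added after these values were seen. The labels give no batch, and no biological explanation was tested.

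The changes shared by sgSik3 and sgMef2c were weighed last. Chance values of the shared sgRosa26 libraries would give a covariance near or below 0 when each knockout is set against a different sgRosa26 library, and it was 0.140 and 0.143 in the 2 assignments, which argues against them as the whole cause. Of the 30 genes lower with YKL-05-099 in RN2, where sgRosa26 takes no part, 26 were also lower in sgMef2c, against 4.65 for independent lists. For these genes, loss of a response that SIK inhibition also lowers fits, by a rule set after the overlap was seen. At most 26 of the 1394 shared falls are covered in this way, and the shared rises are not. A handling difference of the sgRosa26 libraries cannot be told apart from a knockout effect for the wider gene sets, because sgRosa26 is the only control. Those sets did not pass in RN2 with an estimated correlation (camera p = 0.0877 for genes that rose and 0.443 for genes that fell). With an estimated correlation camera called 0 lists in every comparison, so it cannot decide this question. The labels name no batch.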
